A study of Homo sapiens with 24 samples.

How the data were processed

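RNA sequencing libraries were made from total RNA of fresh frozen aortic media, per the labels' protocols, and 24 libraries were analysed. The authors deposited 1 table of expected counts, with 1 column per library and 1 row per gene entry. Expected counts are estimates of the reads that belong to each gene. They need not be whole, because reads shared by similar genes are divided among them, and 10.7% of the table's cells were not whole numbers. STAR, RSEM and edgeR and the builds GRCh38 and hg38 are named per the submitters' processing notes, without role, order or version. The library kit, read length, strand setting, annotation release and any filter are not given in the sources used here. It is therefore not known whether reads of a gene were told apart from those of an antisense gene that overlaps it. Every column was matched to its sample by the name in the sample's title.

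The table held 63925 entries, each a versioned Ensembl gene ID joined to a symbol. Of these, 58039 had their ID in GENCODE 29 on the primary assembly of GRCh38, which gave the chromosome, start and end of each gene named. Further entries were copies of a gene on alternate loci, among which the estimation had divided reads. Entries that shared a symbol as copies were summed, which joined 5618 entries into 1765 genes and left 59552 genes. Y-linked genes, XIST and TSIX (520 entries, 0.119% of all counts) were left out of every library size and test. The summed expected counts were rounded to whole numbers before any count model.

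The total per library lay between 3885240 and 8314223 (median 4611158). A share of about 30% of it fell into 3 unnamed entries on chromosome 21 that lie in ribosomal RNA repeats: FP236383.2 (11.7% of all counts), FP236383.3 (10.7%) and FP671120.3 (8.55%). These and the mitochondrial ribosomal RNAs stayed in the library sizes, and an alternative removed them. At this depth a gene at 1 CPM has only about 4 to 8 counts in a library, so folds of rare transcripts are imprecise.

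The labels give 4 groups of 6 libraries, each numbered 1 to 6. They do not say that a number is a person or that replicates came from separate people, so p-values measure the spread between these samples, whatever its source. The pairing by number was checked from the data over 12486 autosomal genes. Deviations from the group mean correlated between the libraries of 1 condition and 1 number, with r from 0.238 to 0.452 over the 6 aneurysm pairs and from 0.386 to 0.655 over the 6 normal pairs. The median r between different numbers was −0.0672 and −0.0786, and 12 of 12 libraries in each condition correlated best with their own number. The numbers were taken as pairs in aneurysm against normal and in the replicate block below, as had been planned before this check. The main fits of belly against neck, mid against distal ASC and the difference between them took each library as separate. For aneurysm against normal the 2 libraries of a number were summed, which left 6 aneurysm and 6 normal units, so no pair was counted as 2 samples.

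There were 6 comparisons: aneurysm against normal units, belly against mid ASC, neck against distal ASC, belly against neck, mid ASC against distal ASC, and the difference between the last 2. Each was tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM normalization). The filter filterByExpr was used with a minimum count of 10 and a minimum total of 15. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the count with a fold of at least 2 is given beside. Every adjusted p of a gene is edgeR's unless another tool is named. CPM values (counts scaled to a common library total) were computed with TMM-scaled library sizes from the deposited expected counts. Values after ± are SD for CPM and SE for log2 fold changes. That SE is approximate: it is the absolute log2 fold change divided by the square root of edgeR's F statistic. The share of counts in several transcript classes was compared between the 12 units with a two-sided exact permutation test over all 924 assignments.

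A set of 57 gene lists, 17 of them cell type markers, was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 5 members were tested. Adjustment was over the lists tested. Camera with the correlation estimated per list was the alternative, and fry tested whether the members moved one way on balance. A marker list is read as a group of genes and not as a count of cells.

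The genes named were chosen by rule. For aneurysm against normal they came from the 12 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 2. For the other comparisons the number was 6 in each direction. Up to 6 members past the threshold were added from each list described (average log2 CPM of at least 0), as were 18 genes set in advance whether or not they passed. HLA genes, receptor segments, clone names, pseudogenes and small RNAs were not named. The groups, tests, lists, naming rule and the first set of other settings below were chosen before the data were examined. One step departs from that plan, which was to test entries as deposited: copies of a gene were joined, and testing each entry on its own became an added alternative. Of the 18 genes, MMP9 and SOX9 lay below the count filter and were not tested.

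The other settings of that first set were DESeq2 size factors, no count filter, at least 1 CPM in at least 6 libraries or units, DESeq2 1.42.0, limma voom, robust empirical Bayes, 24 separate libraries, a random effect of the pair in limma, all 24 libraries in 1 model, a replicate block and leaving out each unit. Alternatives added after the data had been seen were the entries on their own and removal of ribosomal RNA entries. Others were the replicate block with an estimated correlation and the ribosomal RNA share as a covariate. That share counts the ribosomal RNA repeat entries, without the mitochondrial ribosomal RNAs. For belly and neck, the normal number farthest from the median of the normal numbers on principal component 2 was also left out. Each test was tried on simulated data with 200 genes changed by known folds, all with an average log2 CPM of at least 2. Genes changed 1.5-fold were all raised, and genes changed 2-fold were all lowered. Rarer genes were not changed, so the shares recovered do not cover them. For aneurysm against normal (13862 genes) the test recovered 18% of genes changed 1.5-fold, 74% at 2-fold and 99% at 4-fold. Of its calls 4.61% were false. At 2-fold it recovered 34% for belly against mid ASC, 58% for neck against distal ASC, 70% for belly against neck, 52% for mid against distal ASC and 34% for the difference between the sites' differences. In each simulation 5 of 5 changed lists and 0 of 40 unchanged lists were called. Genes were simulated independently of each other, and every member of the changed lists was raised 4-fold. This result therefore does not tell how camera treats lists of correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.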

Results

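Gene expression was measured by bulk RNA sequencing in the human aortic media, the layer of the aortic wall built mainly of smooth muscle cells and elastic lamellae. The 12 aneurysm libraries came from media labelled as belly or neck of the aneurysm, with 6 libraries each. The 12 normal libraries came from organ donor aortas at sites labelled mid ASC and distal ASC, with 6 each. The labels do not say from which part of the aorta the aneurysms were taken. Mean totals per library were 4645656 ± 399527 counts for belly, 6043641 ± 1712372 for neck, 4624211 ± 654162 for mid ASC and 4555862 ± 541345 for distal ASC (SD, n = 6 libraries each). The stated aim was to compare what smooth muscle cells of the media express in health and in aneurysm.

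Several transcript classes describe the libraries as a whole. Hemoglobin transcripts made up 0.0138% ± 0.0147 of counts in aneurysm units and 0.00124% ± 0.000869 in normal units (SD, n = 6 each; two-sided exact permutation p = 0.00216, the smallest the design allows, adjusted p = 0.0173 over 8 measures). In 1 belly library the share was 0.0677%, and without it the belly mean of 0.0160% was 0.00562% ± 0.00509 (n = 5), against 0.000952% in mid ASC. Mitochondrial ribosomal RNA made up 5.37% ± 0.935 in aneurysm and 7.19% ± 1.59 in normal (n = 6 each; exact p = 0.0238, adjusted p = 0.0952). The ribosomal RNA repeat entries held 30.1% ± 2.40 and 32.4% ± 4.59 (n = 6 each; exact p = 0.316). The 50 highest genes held 51.1% ± 1.48 and 52.9% ± 4.67 (n = 6 each; exact p = 0.422). Protein-coding genes held 63.1% and 58.9% (n = 6 each; exact p = 0.126), and mitochondrially encoded protein-coding genes 0.678% and 0.745% (n = 6 each; exact p = 0.245). The number of genes detected with at least 5 counts was 14170.2 ± 337 in aneurysm and 13818.4 ± 396 in normal (n = 6 each; exact p = 0.126).

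The first comparison asked how aneurysmal media differed from normal media. Of 19 measured genes that glucocorticoids are known to induce, 9 fell in aneurysm and none rose. Of 23 interferon response genes 9 rose, in a list whose call did not hold with an estimated correlation (camera adjusted p = 0.311), and 3 hemoglobin genes rose. FKBP5, a co-chaperone of steroid receptors, fell from 209 ± 36.2 CPM in normal to 37.5 ± 16.0 CPM in aneurysm (SD, n = 6 units each). TNC, the matrix glycoprotein tenascin-C, fell from 315 ± 122 to 42.7 ± 18.8 CPM. VCAM1, a leukocyte adhesion molecule, rose from 7.50 ± 4.47 to 40.3 ± 15.1 CPM, and MYH10, a non-muscle myosin heavy chain, rose from 1284 ± 558 to 3933 ± 633 CPM. The contractile genes ACTA2 and MYH11, by contrast, were not past the threshold of edgeR.

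Of 13862 genes tested with edgeR, 256 rose and 320 fell at an adjusted p under 0.05, and 109 and 138 of them changed at least 2-fold. An unadjusted p under 0.05 was reached by 2966 genes. DESeq2 called 548 genes higher and 643 lower, and these held 253 and 320 of the edgeR calls. The count was smaller without single units: 138 higher and 167 lower without aneurysm replicate 1, 128 and 161 without aneurysm replicate 2, 130 and 161 without aneurysm replicate 3, and 157 and 212 without normal replicate 4. Aneurysm and normal also differ in how the tissue was obtained, since every normal library came from an organ donor.

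The increases given here are the 12 largest that the naming rule allows, among genes past the threshold with an average log2 CPM of at least 2. CCL3 and CCL4, chemokines that attract monocytes and lymphocytes, rose by 3.70 ± 0.657 (adjusted p = 0.00821) and 2.69 ± 0.464 (adjusted p = 0.00727) on the log2 scale. Their reads lay in 3 entries each and may be shared with near-identical paralogs, so these values are uncertain. CX3CR1, the fractalkine receptor of monocytes and cytotoxic lymphocytes (ENSG00000168329.13, chromosome 3, 39263494 to 39281735, GRCh38), rose by 3.29 ± 0.479 (adjusted p = 0.00296), from 0.858 ± 0.800 to 8.93 ± 3.93 CPM. CD83, a marker of activated antigen-presenting cells, rose by 2.71 ± 0.382. VCAM1 (ENSG00000162692.10, chromosome 1, 100719742 to 100739045) rose by 2.41 ± 0.354. SCG2, a secretory granule protein, rose by 3.04 ± 0.612, and CEMIP, which takes part in hyaluronan breakdown, by 2.50 ± 0.491. PGAM2, a muscle enzyme of glycolysis, rose by 2.97 ± 0.768 (adjusted p = 0.0440), and SLC26A4, an anion exchanger, by 2.67 ± 0.538. HBA2, HBA1 and HBB, the 3 measured members of the red blood cell list, rose by 3.59, 3.46 and 3.28, beside the higher hemoglobin share given above. HBA1 and HBA2 are near-identical copies, so the division of reads between them is uncertain.

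**Figure D1:**
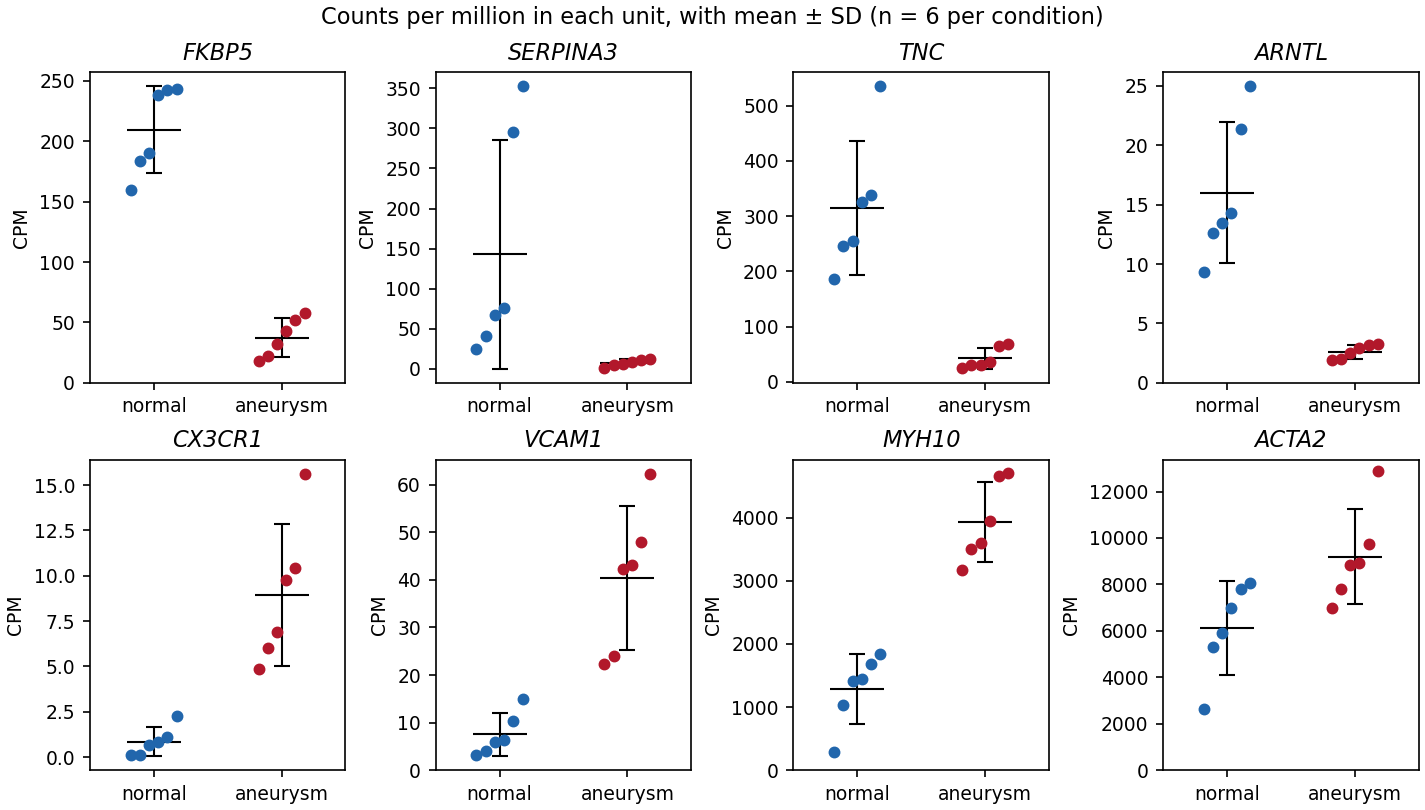
Expression in CPM (vertical axes, linear) of 8 genes in 6 normal and 6 aneurysm units, where each point is 1 unit made of 2 libraries, the long line the mean and the bar 1 SD. FKBP5, SERPINA3, TNC and ARNTL lay lower in every aneurysm unit than in any normal unit, CX3CR1, VCAM1 and MYH10 lay higher in every aneurysm unit, and ACTA2 overlapped (log2 fold change 0.59, adjusted p = 0.189).

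The decreases were chosen by the same rule, and the one of them not named here, FKBP5, is given with its list. SERPINA3, a secreted acute-phase protease inhibitor (ENSG00000196136.17, chromosome 14, 94612377 to 94624055), fell by 4.21 ± 0.683 (adjusted p = 0.00543), from 143 ± 143 to 7.81 ± 4.23 CPM. SAA1, an acute-phase serum amyloid protein with a close paralog, fell by 3.33 ± 0.710. IL1R2, the decoy receptor for interleukin-1, fell by 4.22 ± 0.720, a call that limma voom did not make (adjusted p = 0.0665). ISM1, a secreted inhibitor of angiogenesis, fell by 3.90 ± 0.492. PHYHIP fell by 2.99 ± 0.533, MYZAP, a protein of muscle cell junctions, fell by 2.63 ± 0.524, and HS3ST2, a heparan sulfate sulfotransferase, fell by 2.56 ± 0.470. TNC (ENSG00000041982.15, chromosome 9, 115019578 to 115118257) fell by 2.88 ± 0.305 (adjusted p = 0.000354). SLC11A1, a metal transporter of phagocytes, fell by 2.82 ± 0.361, and S100A9, an abundant neutrophil and monocyte protein, fell by 2.52 ± 0.630. ARNTL, which encodes the clock transcription factor BMAL1, fell by 2.60 ± 0.248 and had the smallest adjusted p of the comparison (0.000312).

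In the glucocorticoid response list, 9 of 19 measured members fell and none rose, against 14 lower when adjusted over the list alone. The list had a median log2 fold change of −1.13 (camera adjusted p = 1.75e-20, and adjusted p = 0.0422 with an estimated correlation). It was the one list of 53 tested whose call held with an estimated correlation. FKBP5 (ENSG00000096060.14, chromosome 6, 35573585 to 35728583) fell by 2.48 ± 0.260 (adjusted p = 0.000354). MT1X, a metallothionein with near-identical family members, fell by 2.22 ± 0.430. ERRFI1, a feedback inhibitor of the EGF receptor, fell by 2.02 ± 0.228, CRISPLD2 fell by 1.92 ± 0.402, the transcription factor gene CEBPD fell by 1.82 ± 0.248 and GLUL, glutamine synthetase, fell by 1.32 ± 0.185. Of the 4 measured metallothioneins, 2 fell (median −1.35, too few for camera, 3 lower when adjusted over the list alone).

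In the interferon response list, 9 of 23 measured members rose and none fell, against 15 higher when adjusted over the list alone. Its median log2 fold change was 0.89 (camera adjusted p = 2.57e-11, but adjusted p = 0.311 with an estimated correlation). CXCL10 and CXCL9, chemokines for activated T cells, rose by 3.87 ± 0.429 and 3.32 ± 0.750, from mean levels of 0.208 and 0.349 CPM. RSAD2 rose by 1.64 ± 0.337, OAS3, an activator of antiviral RNA decay, by 1.46 ± 0.281 and IFIT2 by 1.22 ± 0.229. Among the 10 antigen presentation genes, CD74, the invariant chain of MHC class II, rose by 1.32 ± 0.283, and it was the single gene called, also when adjusted over the list alone. That list's median was 0.34 (camera adjusted p = 0.00387, but adjusted p = 0.823 with an estimated correlation). The inflammatory cytokine and NF-kB list had 3 of 19 members higher, 4 higher and 1 lower when adjusted over the list alone, a median of 0.07 and a camera adjusted p of 0.0565. Leaving out 1 unit at a time, camera called it in 6 of 12 fits (adjusted p from 0.000434 to 0.129, medians from −0.00582 to 0.33).

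**Figure D2:**
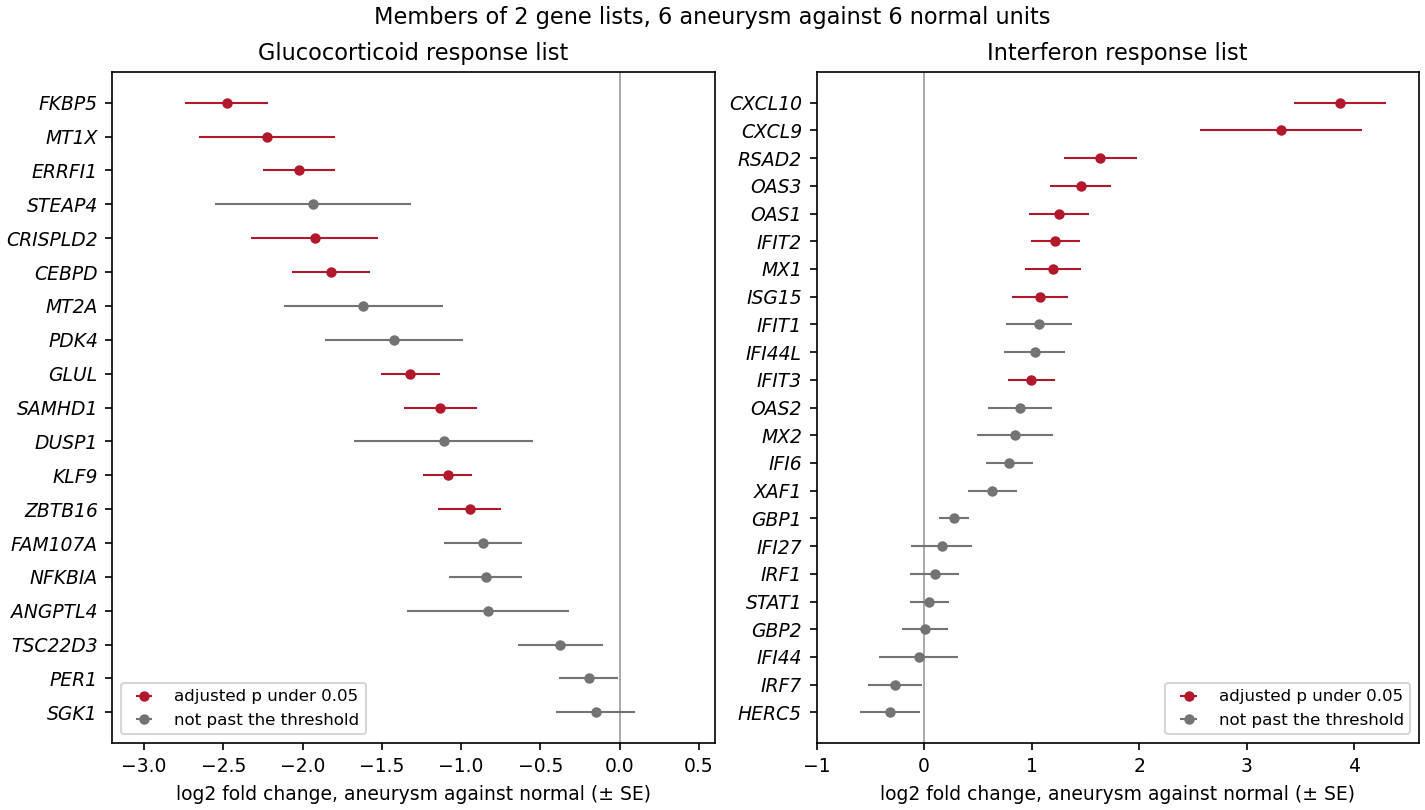
Log2 fold change of aneurysm against normal with its SE (horizontal axes) for each measured member of the glucocorticoid response list (left) and the interferon response list (right), from 6 units per condition. Red points passed an adjusted p under 0.05 (9 of 19 members, all lower, and 9 of 23 members, all higher) and grey points did not.

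Smooth muscle contractile genes were not called as a group: 1 of 37 measured members rose, 36 were not past the threshold, and the median was 0.07 (camera adjusted p = 0.357, 2 higher and 1 lower when adjusted over the list alone). The gene that rose was MYOCD, the coactivator of contractile gene transcription, by 0.67 ± 0.170 (adjusted p = 0.0404). ACTA2, smooth muscle actin, had a log2 fold change of 0.59 ± 0.249 (adjusted p = 0.189), and MYH11, smooth muscle myosin, of 0.56 ± 0.223 (adjusted p = 0.164). With the pair as a random effect limma voom called both higher (adjusted p = 0.0482 and 0.0335). TAGLN had 0.13 (adjusted p = 0.771) and CNN1 −0.16 (adjusted p = 0.758). In the cytoskeleton and focal adhesion list, 2 of 34 members rose and 3 fell, against 2 and 6 when adjusted over the list alone (median −0.02, camera adjusted p = 0.468). MYH10 (ENSG00000133026.12, chromosome 17, 8474205 to 8630761) rose by 1.61 ± 0.322 (adjusted p = 0.0141) and VIM, vimentin, by 0.83 ± 0.202. ITGA5, the fibronectin receptor subunit, fell by 1.80 ± 0.268, and RHOB, a small GTPase, fell by 1.34 ± 0.234. KLF4, a transcription factor of smooth muscle phenotype change, had a log2 fold change of −0.07 (adjusted p = 0.903), RUNX2 of −0.16 (adjusted p = 0.913) and SPP1 of −0.22 (adjusted p = 0.890).

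Matrix genes moved both ways. In the proteoglycan and hyaluronan list, 3 of 25 members rose and 1 fell, against 4 and 3 when adjusted over the list alone (median 0.16, camera adjusted p = 0.112). VCAN, the large proteoglycan versican, rose by 1.31 ± 0.282, OGN by 1.21 ± 0.232 and HAPLN1, a hyaluronan link protein, by 0.92 ± 0.234, while the versican- and aggrecan-cleaving protease ADAMTS4 fell by 2.17 ± 0.560. In the list of matrix proteases and inhibitors, 1 of 23 rose and 3 fell, against 2 and 5 when adjusted over the list alone (median −0.02, camera adjusted p = 0.399). MMP2, gelatinase A, rose by 0.80 ± 0.203, MMP19 fell by 1.09 ± 0.232 and TIMP4, an inhibitor of metalloproteinases, fell by 2.21 ± 0.284. BMP1, the procollagen C-proteinase, fell by 1.44 ± 0.161 and was the single member of 23 called in the fibrillar collagen list, against 4 higher and 4 lower when adjusted over the list alone (median −0.01, camera adjusted p = 0.929). MFAP4, a microfibril protein, rose by 0.82 ± 0.218 and was the single member of 24 called in the elastic fibre list, against 3 higher and 1 lower when adjusted over the list alone (median 0.02, camera adjusted p = 0.357). ELN, elastin, had a log2 fold change of −1.09 ± 0.345 (adjusted p = 0.0873), which DESeq2 called (adjusted p = 0.0190). FBN1 had 0.07, COL1A1 0.05, COL3A1 −0.24 and LOX −0.13, none past the threshold. Of 21 basement membrane genes, LAMA2 fell by 0.88 ± 0.235 and LAMB1 fell by 0.75 ± 0.199, the same 2 calls when adjusted over the list alone (median −0.11, camera adjusted p = 0.322).

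Growth factor pathways moved in single genes. None of the 29 heritable thoracic aneurysm genes passed, also when adjusted over the list alone (edgeR, median 0.03, camera adjusted p = 0.399). Of 19 TGF-beta ligands, receptors and SMADs, TGFBR3, a co-receptor, fell by 0.90 ± 0.212, the one call also when adjusted over the list alone (median −0.05, camera adjusted p = 0.950). TGFBR1 had a log2 fold change of −0.06 (adjusted p = 0.903) and TGFBR2 of −0.49 (adjusted p = 0.165). In the BMP pathway, with 1 of 20 members higher and 1 lower, the antagonists FST and CHRD changed by 1.58 ± 0.416 and −1.17 ± 0.301 (camera adjusted p = 0.562). DUSP6, a feedback phosphatase of ERK signalling, rose by 1.17 ± 0.280 and was the one of 16 FGF pathway members called (camera adjusted p = 0.567). Of 17 Wnt pathway genes, 1 rose and AXIN2, a feedback target, fell by 1.16 ± 0.236 (camera adjusted p = 0.222). When adjusted over the list alone, 2 higher and 1 lower were called for the BMP list, 3 higher for the FGF list, and 2 higher and 1 lower for the Wnt list. Of 23 immediate early genes, 1 rose, EGR2 by 1.84 ± 0.407, and 1 fell (camera adjusted p = 0.842, 1 higher and 2 lower when adjusted over the list alone). Of 20 heat shock genes, HSP90AB1 rose by 0.65 ± 0.126, the one call also when adjusted over the list alone (camera adjusted p = 0.143).

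Marker genes of cell types gave no single direction. The adipocyte list had 2 of 10 members lower, 5 when adjusted over the list alone, and a median of −1.39 (camera adjusted p = 0.00412, but adjusted p = 0.823 with an estimated correlation, 0.0506 without normal replicate 6 and 0.0624 with the ribosomal RNA share as a covariate). Its 2 called members were LPL, lipoprotein lipase, which fell by 1.75 ± 0.465, and SAA1, which is also an acute-phase gene. The 26 macrophage markers had a median of −0.01 (camera adjusted p = 0.322), and the single one called was CD163, a hemoglobin scavenger receptor that glucocorticoids are known to induce, which fell by 2.36 ± 0.373. When adjusted over the list alone, 3 macrophage markers were higher and 1 was lower. The 6 neutrophil markers had a median of −1.17 (1 lower, S100A9, and 2 when adjusted over the list alone, camera adjusted p = 0.222), and the 8 T and NK cell markers a median of 0.69 (none past the threshold in edgeR, also when adjusted over the list alone, camera adjusted p = 0.212). Single units moved these calls: without aneurysm replicate 1 the T and NK cell markers had a median of 1.08 and were called (camera adjusted p = 0.0123), without aneurysm replicate 4 it was 0.49, and without normal replicate 3 the macrophage markers had 0.27 and were called (adjusted p = 0.0179). The median of the neutrophil markers lay between −1.38 and −0.68 without 1 unit (adjusted p from 0.0506 to 0.505). Of 19 endothelial markers, KDR, the VEGF receptor, fell by 1.09 ± 0.186, the one call also when adjusted over the list alone (median −0.43, camera adjusted p = 0.268). Without 1 unit that median lay between −0.58 and −0.12, and camera called the list in 1 of 12 fits (adjusted p = 0.0446). Of 21 fibroblast and adventitia markers, 2 rose, 3 higher and 1 lower when adjusted over the list alone, with SFRP4, a secreted Wnt modulator, at 1.30 ± 0.258 (camera adjusted p = 0.573). KIT, a mast cell marker, fell by 1.29 ± 0.330, and ALPL, an osteoblast marker, fell by 2.27 ± 0.424, in lists with camera adjusted p of 0.491 and 0.861 and 1 member called lower in each. Adjusted over the list alone, 1 mast cell marker was higher and 1 lower, as were 1 and 1 of the osteoblast markers.

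**Figure D3:**
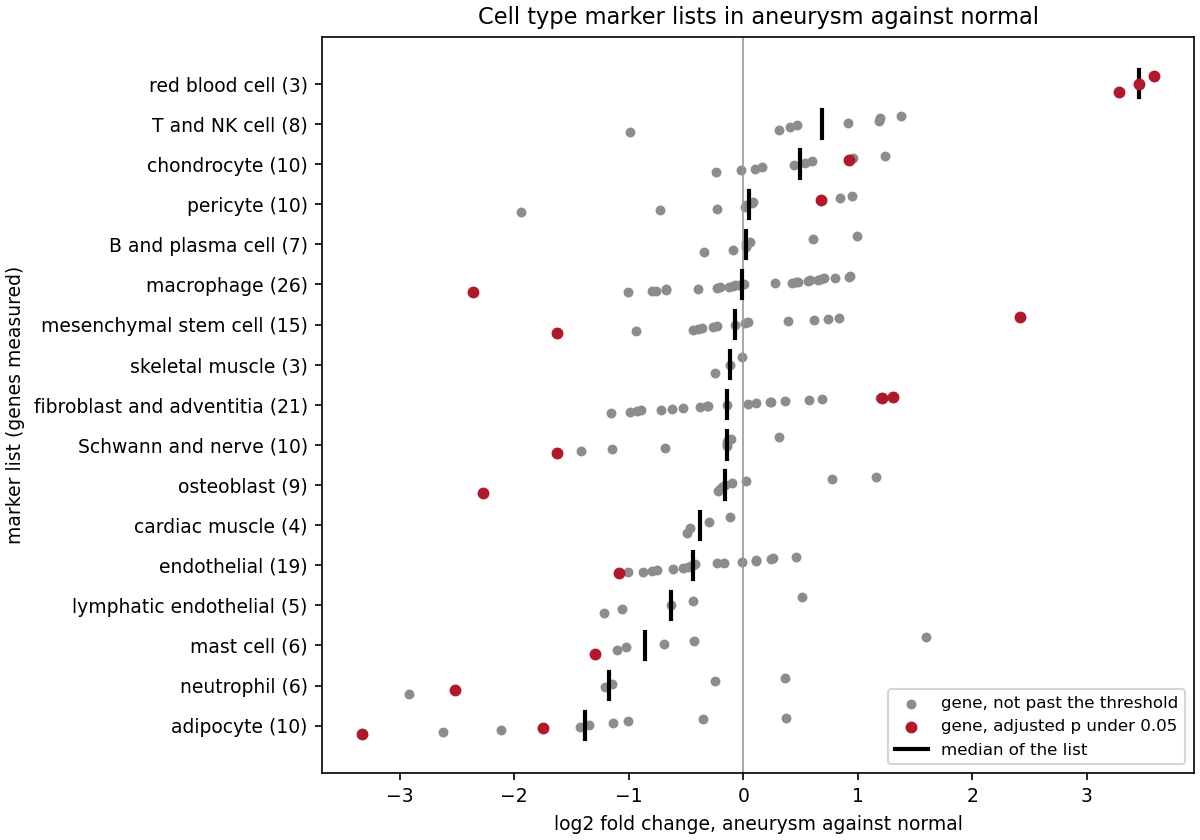
Log2 fold change of aneurysm against normal (horizontal axis) for each measured gene of 17 cell type marker lists (rows, with the number of genes measured), from 6 units per condition, where red points passed an adjusted p under 0.05 and black lines mark list medians. Medians ranged from −1.39 for adipocyte markers to 3.46 for the 3 red blood cell markers, and that of the macrophage markers was −0.01.

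Another 2 lists moved by small amounts with no single gene past the edgeR threshold, also when adjusted over the list alone. The 66 cytosolic ribosomal protein genes had a median of 0.28 with 64 above 0 (camera adjusted p = 7.52e-08, but adjusted p = 0.823 with an estimated correlation). The 21 cholesterol synthesis genes had a median of 0.29 with 18 above 0 (camera adjusted p = 0.0471, but adjusted p = 0.823 with an estimated correlation, 0.185 with the ribosomal RNA share as a covariate, and not called in 8 of 12 fits without 1 unit). Mitochondrial ribosomal RNA made up 5.37% in aneurysm and 7.19% in normal (exact permutation test, adjusted p = 0.0952), and whether this share bears on either list was not tested. Of the 53 lists tested, 4 were called in each of the 12 fits without 1 unit, 36 in none and 13 in some. Of the 64 genes named above as changed, 18 lost the call without at least 1 of the 12 units: PGAM2, LPL, ADAMTS4, FST, KIT, LAMA2, LAMB1, MFAP4, S100A9, MYOCD, CHRD, HAPLN1, VIM, MMP2, TGFBR3, DUSP6, CXCL9 and EGR2. Another 4 (HBA1, SLC26A4, IL1R2 and CD74) lost it in other settings only, and 42 kept it in all settings in which single genes were followed, which leaves out the test of each entry on its own.

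The next comparisons each set 1 aneurysm site against 1 normal site: belly against mid ASC and neck against distal ASC. The labels do not match these sites, so condition and place cannot be told apart in either comparison. In both comparisons SERPINA3 and TNC fell and CX3CR1 rose, also in each of 9 other settings. HBA2 and SCG2 also rose in both, but limma voom and robust empirical Bayes did not call HBA2 in belly (adjusted p = 0.145 and 0.0643) or neck (0.0642 and 0.0718), nor SCG2 in belly (0.142 and 0.0637). Belly against mid ASC called 122 genes higher and 152 lower of 12126 tested, 73 and 78 of them by at least 2-fold. HBA2 rose by 4.19 ± 0.904, from 4.05 ± 2.24 to 72.0 ± 120 CPM with 1 belly library far above the rest, though all 6 lay above every mid ASC library. SCG2 rose by 3.21 ± 0.693, CX3CR1 by 3.19 ± 0.564, from 0.845 ± 0.897 to 8.82 ± 4.66 CPM (n = 6 each), CD83 by 2.58 ± 0.394 and VCAM1 by 2.53 ± 0.387. ISM1 fell by 4.22 ± 0.536, SERPINA3 fell by 4.11 ± 0.713 and SAA1 fell by 3.25 ± 0.619. TNC fell by 2.87 ± 0.472, from 312 ± 153 to 42.7 ± 31.7 CPM. PHYHIP fell by 2.85 ± 0.574, a call that limma voom did not make (adjusted p = 0.0807). DESeq2 called 327 genes higher and 394 lower.

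Neck against distal ASC called 150 genes higher and 155 lower of 12193 tested, 85 and 91 of them by at least 2-fold. CCL3 rose by 3.58 ± 0.613, CX3CR1 by 3.36 ± 0.480, CCL4 by 3.18 ± 0.616 and SCG2 by 2.94 ± 0.555, of which limma voom did not call CCL4 (adjusted p = 0.0523). HBA2 rose from 5.94 ± 5.36 to 47.5 ± 33.9 CPM (adjusted p = 0.0288). SERPINA3 fell by 4.15 ± 0.650, PHYHIP fell by 3.10 ± 0.502, SLC11A1 fell by 2.91 ± 0.464 and ARNTL fell by 2.73 ± 0.296. S100A9 fell by 2.84 ± 0.726 (adjusted p = 0.0498), a call lost in 6 of 9 other settings, among them limma voom (adjusted p = 0.181) and robust empirical Bayes (0.109). TNC fell by 2.86 ± 0.240 (adjusted p = 2.71e-05), from 302 ± 99.4 to 41.6 ± 11.5 CPM. DESeq2 called 340 genes higher and 398 lower, and 74 distinct genes were higher when each deposited entry was tested on its own. Of 11937 genes tested in both comparisons, 60 were higher and 72 lower in both, and 0 were called in opposite directions. Independent lists of these sizes would share 1.47 and 1.94 genes, but both comparisons draw on the same label numbers, so the excess is no independent repeat.

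The fourth comparison asked how the belly of an aneurysm differed from its neck. In the main fit, which leaves out the pairing, no single gene was past the threshold. Gene lists differed there by medians of under a log2 unit. Hypoxia and glycolysis genes had a median of −0.28 in belly over 25 members, endothelial markers of −0.27 over 18, and fibroblast and adventitia markers of 0.21 over 21 (camera adjusted p = 1.24e-09, 4.90e-05 and 0.000344). With an estimated correlation their adjusted p were 0.504, 0.648 and 0.648. The other lists called lower were cholesterol synthesis (−0.31), immediate early genes (−0.43), heat shock (−0.23), nuclear oxidative phosphorylation (−0.12), cytosolic ribosomal proteins (−0.14) and smooth muscle contractile genes (−0.09). Those called higher were interferon response (0.21), mitochondrially encoded genes (0.17) and macrophage markers (0.17), and for these 9 lists the adjusted p with an estimated correlation lay between 0.648 and 0.806. With edgeR 0 of 12210 genes passed, with 290 at an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. With the replicate block edgeR called 1 gene, ESAM, an adhesion molecule of endothelial tight junctions, which is named after its values were seen. ESAM (ENSG00000149564.11, chromosome 11, 124752583 to 124762290) had a log2 fold change of −0.99 ± 0.145 in belly against neck (edgeR adjusted p = 0.0406 with the block), and of −0.98 ± 0.309 without the block, not past the threshold (unadjusted p = 0.00588).

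The fifth comparison asked how mid ASC differed from distal ASC in normal aorta. Endothelial markers had a median of −0.36 in mid ASC over 19 members and mitochondrially encoded genes of −0.29 over 13 (camera adjusted p = 1.92e-05 and 1.40e-06). Adipocyte markers (0.69), macrophage markers (0.37) and fibrillar collagen genes (0.10) were called higher. All 5 lists had an adjusted p of 0.969 with an estimated correlation, and the replicate block called 12 lists with the preset correlation and 0 with an estimated one. With edgeR 0 of 12058 genes passed, with 111 at an unadjusted p under 0.05, and DESeq2, limma voom and the replicate block also called 0.

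The last comparison asked whether the difference of belly from neck differed from that of mid from distal ASC. The sites compared in aneurysm and in normal aorta are not the same, so the contrast sets 1 pair of sites against another. Mitochondrially encoded genes had a median difference of 0.46 over 13 members and hypoxia and glycolysis genes of −0.29 over 26 (camera adjusted p = 2.41e-06 and 1.89e-05). Their adjusted p with an estimated correlation were 0.873 and 0.828. A further 7 lists were called with the preset correlation, with medians from −0.86 for adipocyte markers to 1.07 for neutrophil markers, and their adjusted p with an estimated correlation were 0.873 or 0.898. The replicate block called 16 lists with the preset correlation and 0 with an estimated one. With edgeR 0 of 13030 genes passed, with 283 at an unadjusted p under 0.05, and DESeq2, limma voom and the replicate block also called 0.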

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

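The test of gaps within groups, the tests of the site difference and the regroupings of samples given here were all fixed before their results were seen.

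In 9 of 236 groups of 6 values, 1 value lay apart from the other 5 by more than Dixon's critical share of the group's range, where chance gives 11.8 such groups. One normal unit lay high for SCG2 (gap 0.684 of the range), and 1 mid ASC library did for the same gene (0.706). One normal unit lay low for MYH10 (0.689) and 1 for MYH11 (0.667). The unit low for MYH10 was normal replicate 3 (291 CPM), the normal number farthest on principal component 2. Of the normal units it also had the lowest ACTA2 (2636 CPM) and the highest TNC (535), SERPINA3 (352), VCAM1 (15.1) and CX3CR1 (2.28). FKBP5 and ARNTL lay within the range of the other normal units. MYH10 kept its call in all 22 other settings, with log2 fold changes from 1.40 to 1.80. These values were picked after the gap was seen. Among aneurysm units, 1 lay low for MFAP4 (0.630), 1 low for FST (0.690) and 1 high for LPL (0.652). The hemoglobin share of counts was high in 1 belly library (0.814) and in 1 distal ASC library (0.658).

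For the site differences the main fit leaves out the pairing, and the replicate block called 16 lists with the preset correlation and 0 with an estimated one. In the main fit the site difference of aneurysm (belly minus neck) differed from that of normal aorta (mid minus distal ASC) in 9 gene lists by camera with the preset correlation, and in none with an estimated one (adjusted p between 0.828 and 0.898). Medians of this difference on the log2 scale were 1.07 for neutrophil markers (camera adjusted p = 0.0164), 0.459 for mitochondrially encoded genes (adjusted p = 2.41e-06) and 0.298 for interferon response genes (adjusted p = 0.0164). They were −0.858 for adipocyte markers (adjusted p = 0.0164), −0.467 for immediate early genes (adjusted p = 0.00951), −0.286 for hypoxia and glycolysis (adjusted p = 1.89e-05), −0.257 for cholesterol synthesis (adjusted p = 0.0164), −0.206 for heat shock (adjusted p = 0.000128) and −0.127 for nuclear oxidative phosphorylation (adjusted p = 0.00434).

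Other groupings of the same samples were set against each count of genes. For aneurysm against normal chance is unlikely to account for the count. Of 100 splits of the 12 units tried, among 462 possible, 1, the real one, gave as many genes (576 against a highest other of 66). Chance is likewise unlikely for belly against mid ASC (1 of 100 splits, 274 against 145) and for neck against distal ASC (1 of 100, 305 against 3). Here too 462 splits were possible. Between the sites chance cannot be excluded. With the replicate block, belly against neck gave 572 genes at an unadjusted p under 0.05, and 13 of the 32 ways to exchange sites within pairs gave as many, up to 1261. Mid against distal ASC gave 473 genes, and 14 of 32 exchanges gave as many, up to 1603. The difference between the site differences gave 691 genes, and 18 of 60 exchanges of whole pairs between the conditions gave as many, up to 1421.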

How the results depend on the processing

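Alternatives chosen after the data had been seen were testing each entry on its own, removing ribosomal RNA entries, the ribosomal RNA share as a covariate and the replicate block with an estimated correlation. Another was leaving out normal replicate 3 for belly against mid ASC and neck against distal ASC. For aneurysm against normal (256 genes higher, 320 lower), DESeq2 called 548 and 643, taking the 24 libraries as separate 1008 and 1073, limma voom with the replicate block as a random effect of the pair 575 and 491, and the ribosomal RNA share as a covariate 195 and 209. The 24 libraries count each pair as 2 samples, which makes that count too large. For the other settings the cause was not tested. Leaving out 1 unit gave 128 to 369 higher and 161 to 350 lower, with fewer samples. The units that moved a count by over 1.5 times were aneurysm replicate 1 (138 and 167), 2 (128 and 161) and 3 (130 and 161) and normal replicate 4 (157 and 212). For belly against mid ASC (122 and 152), no count filter gave 203 and 271, DESeq2 327 and 394, and the model of all 24 libraries 186 higher. For neck against distal ASC (150 and 155), no count filter gave 248 and 270, DESeq2 340 and 398, and single entries 74 higher. The cause was not tested. The filter of 1 CPM in 6 libraries, planned as stricter, kept more genes than the one it replaced (13951 against 13862 for aneurysm against normal) and is a test of a laxer filter.

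The replicate block gave 1 gene lower in belly than in neck in place of 0, and with the preset correlation 15 lists for belly against neck, 12 in place of 5 for mid against distal ASC and 16 in place of 9 for the difference between site differences. No other count of genes changed with the block. With an estimated correlation 1 list was called for aneurysm against normal in place of 6, and 0 for each of the other 3 comparisons, with or without the block. Between the sites every count of genes stayed at 0 under the other alternatives run (edgeR, DESeq2 and limma voom).

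Of the genes named in the report for aneurysm against normal, the 18 set in advance include those whose sign changed, none of them past the threshold. KLF4 had 0.0150 with limma voom, and SPP1 0.23 with limma voom and 0.30 with the replicate block as a random effect. With the ribosomal RNA share as a covariate COL1A1 had −0.0041 and RUNX2 0.19. Leaving out 1 unit gave −0.62 to 0.61 for RUNX2, −0.00917 to 0.15 for FBN1, −0.0683 to 0.14 for COL1A1, −0.16 to 0.0619 for TGFBR1, −0.20 to 0.17 for KLF4, −0.68 to 0.50 for SPP1, −0.33 to 0.0150 for CNN1 and −0.29 to 0.0728 for LOX. The cause was not tested. The median of the glucocorticoid response list lay between −1.24 and −1.06 without each of the 12 units in turn (highest camera adjusted p = 9.82e-17) and was −0.998 with the ribosomal RNA share as a covariate. That of the interferon response list lay between 0.644 and 1.01 (1.35e-08) and was 0.972. So neither 1 unit nor the share of the ribosomal RNA repeat entries carries these changes. The share of mitochondrial ribosomal RNA was not tried as a covariate. ACTA2 and MYH11 passed with 24 separate libraries (adjusted p = 0.0346 and 0.0232) and with the replicate block as a random effect (limma, 0.0482 and 0.0335). Over the 79 genes followed through these settings, 102 when counted in each comparison, 807 of 960 values with 1 unit left out kept sign and call, 137 lost the call, 1 gained it and 15 changed sign. Under the other alternatives 897 of 967 kept both, 58 lost the call, 7 gained it and 5 changed sign. At totals of 3885240 to 8314223 counts, 18% of genes raised 1.5-fold were found in simulated data for aneurysm against normal. Those genes had an average log2 CPM of at least 2.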

Other observations

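Tests chosen only after the result was seen are those of macrophages, neutrophils, adipocytes, T and NK cells and organ donor state. The tests of the clock genes were set before their results were seen.

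Several genes of the cell's daily clock changed in aneurysm against normal, 7 of the 14 looked at. They are named here after their values were seen. All of the called genes but HLF were picked with their values known, so the share of 7 in 14 is no test. Beside ARNTL (log2 fold change −2.60 ± 0.248), its partner NPAS2 fell by 1.30 ± 0.265 (edgeR adjusted p = 0.0154) and NFIL3, a repressor, fell by 1.75 ± 0.235 (adjusted p = 0.00182). CLOCK had −0.48 (adjusted p = 0.0702). PER2, PER3 and CIART, genes that the ARNTL protein activates and that act against it, rose by 1.38 ± 0.197, 1.62 ± 0.220 and 1.69 ± 0.315 (adjusted p = 0.00263, 0.00190 and 0.0109). PER1, which glucocorticoids also induce, had −0.20 (adjusted p = 0.584).

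For the clock genes a candidate explanation is tissue taken at another phase of the daily clock. Of 6 more genes of the phase opposite to ARNTL (NR1D1, NR1D2, DBP, TEF, HLF and BHLHE41), 6 were above 0, with a median of 0.817, and 1 passed the threshold (HLF, 0.83, adjusted p = 0.0404), as that explanation predicts. The tables argue against 1 unit carrying the difference, since the highest adjusted p of ARNTL without each unit in turn was 0.00140. Of the opposite-phase genes already seen in these units, PER2, PER3 and CIART were higher and PER1 was not, so a rise of the 6 was likely beforehand. They cannot tell another sampling phase from a change of the clock in diseased media. Such a change stays open and was not tested, since no sampling times were used.

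For the lower glucocorticoid response genes, the tables argue against fewer macrophages as a whole. Their 26 markers had a median log2 fold change of −0.0132 with an SD of 0.750 over members. That is short of the list's −1.13 by 1.12, and by at least 1.01 without each unit in turn. The median cannot decide on a part of the macrophages, since CD163, the single marker called, fell by 2.36. Fewer neutrophils and a fall within other cells cannot be told apart, since the 6 neutrophil markers, too few to decide, had a median of −1.17 with an SD of 1.27 (camera adjusted p = 0.222), and of −1.38 to −0.68 without 1 unit (0.0506 to 0.505). Nor can fewer adipocytes be told apart from it, since the 10 adipocyte markers fell with the list (median −1.39, camera adjusted p = 0.00412), a call lost without normal replicate 6 (0.0506) and with an estimated correlation (0.823). The state or treatment of organ donors before sampling may have raised these genes, together with the acute-phase genes SERPINA3 and SAA1, in the normal tissue. That hypothesis and an effect of aneurysm cannot be told apart, since in 0 of 24 libraries was normal aorta from another source than an organ donor.

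For the higher interferon response genes, more macrophages and a rise within other cells cannot be told apart: the same marker median of −0.0132 lies below the list's 0.89 by more than the SD of 0.750, but in 4 of 12 fits without 1 unit the gap was smaller than that SD (down to 0.66), and without normal replicate 3 camera called the markers higher (median 0.27, adjusted p = 0.0179). More T and NK cells stay open likewise and cannot be told apart from such a rise, since the 8 T and NK cell markers had a median of 0.69 (camera adjusted p = 0.212), and of 1.08 without aneurysm replicate 1 (0.0123). The state or treatment of organ donors before sampling may have lowered these genes in the normal tissue, which cannot be told apart from an effect of aneurysm for the reason given above (0 of 24 libraries). A response of the cells of the media to interferon in aneurysm also stays open, and it was not tested, since bulk libraries do not say which cells hold the transcripts. The list's call did not hold with an estimated correlation (adjusted p = 0.311).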
